A study of Mus musculus with 6 samples.

How the data were processed

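Poly(A) RNA of mouse splenic B cells was sequenced in 6 libraries. Wild-type C57BL/6 B cells had been selected with CD19 beads, per the labels' protocols, and cultured for 72 hours with lipopolysaccharide (LPS, a bacterial ligand of the receptor TLR4) at 50 μg/ml or with an antibody against CD40 at 1 μg/ml together with interleukin 4 (IL4) at 20 ng/ml. The library kit keeps strand information, per the labels' protocols. The reads were processed on the mouse build mm9, per the submitters' processing notes. The aligner, the counting tool, the gene annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here.

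The authors deposited 1 table of raw counts, with 21761 genes in rows, 1 column per library and a gene length that entered no test. The values were whole numbers that summed to between 28312688 and 33910906 per library, and no normalization was found in them. Rows carried numeric gene IDs. Symbols came from a RefSeq gene table on GRCm38.p6, which matched 21615 of the IDs, and from GENCODE M21, which named 7 more. The 139 rows without a symbol held 0.0700% of all counts. Because the reference and the files use different builds, only names were taken from the reference and no coordinates are given. Immunoglobulin constant and variable gene segments were not analysed here. Gapdh, which every cell uses, had between 14 and 27 counts per library, so low values of genes with many near-identical copies cannot be read as low expression. Counts of near-identical genes such as Hspa1a and Hspa1b are uncertain in their split. Since the strand setting is not given, overlapping antisense pairs such as Xist and Tsix may not be separated.

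Gene tests used edgeR 4.0.16 in R 4.3.3. Genes passed the default expression filter (filterByExpr by group, minimum count 10, minimum total 15), which left 11957 genes. Library sizes were scaled by trimmed mean of M values (TMM) factors, and the quasi-likelihood F-test compared the 3 anti-CD40/IL4 libraries with the 3 LPS libraries, with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was an adjusted p of 0.05. A second count required a log2 fold change of at least 1 in either direction. Fold changes are anti-CD40/IL4 minus LPS, as fitted by edgeR with its default prior count, and each standard error (SE) is the fold change divided by the square root of its F statistic. Levels are TMM-scaled CPM, given as mean ± SD over 3 libraries. For genes with 1 to 3 counts in a whole group, the ratio of counts is given with an exact 95% interval. A count of 0 allows up to 3 counts, which is 0.0885 to 0.106 CPM per library. Such intervals and floors cover counting error only.

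Gene lists were fixed before the data were examined: 31 lists with 639 distinct genes, of which 17 had no row under a matching symbol and 4 list entries were found under another symbol. The 24 lists with at least 5 tested members were tested with camera (limma 3.58.1), which compares a list with all other genes, at a preset inter-gene correlation of 0.01. The test was repeated with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way and compares them with no other genes. Genes are named by a rule also fixed before the data were examined. It takes 10 genes of the octamer-factor, germinal centre and plasma cell networks, and the 8 genes with the largest fold change in each direction with a mean of at least 10 CPM and groups that did not overlap. From each list it takes the 2 members with the smallest adjusted p in each direction, and from lists of other cell types also the 2 most abundant members.

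On counts simulated from the real means, library sizes and dispersions of this comparison, the gene test recovered 30% of genes changed by 0.1 on the log2 scale, 60% at 0.25, 90% at 0.5 and 94% at 1. It called 0.0682% of 11727 unchanged genes, with 11828 genes tested. The simulation left most genes unchanged and used the dispersions fitted to these libraries. It therefore covers neither errors of scaling when most genes differ nor a larger spread between cultures.

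Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. Replicates of a group differed by more than counting noise. The chi-square per degree of freedom was 1.37 to 2.23 within groups, with a largest chi-square p of 2.79e-139, over genes with at least 20 counts in a pair. No library was therefore merged with another as a repeat deposit, but repeat libraries of 1 culture can also differ by this much, so the test does not show separate cultures.

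The alternatives were DESeq2 1.42.0 size factors, upper-quartile factors or library totals in place of TMM, no filter beyond a total of 0, a filter of 10 CPM in 3 libraries, the DESeq2 Wald test, limma-voom, the replicate number as a block, and the omission of each library in turn. A further pair was chosen after seeing the data: edgeR's glmTreat against a log2 fold change of 1, and an assumed biological coefficient of variation of 0.2.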

Results

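The data were gene counts from 6 RNA-seq libraries of mouse CD19+ splenic B cells after 3 days in culture. For 3 libraries the cells had received anti-CD40 with IL4, which stands in for help from T cells. For the other 3 they had received LPS, which activates B cells through TLR4 without T cell help. Total counts were 29484491, 28707515 and 28312688 in anti-CD40/IL4 replicates 1 to 3 and 30677546, 33910906 and 33300188 in LPS replicates 1 to 3. The only comparison in the design is anti-CD40/IL4 against LPS. The series concerns the coactivator OBF1, the octamer-binding (Oct) factors and the germinal centre programme, and this comparison shows how those genes and the rest of the transcriptome differ between the 2 stimuli.

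B cells given anti-CD40/IL4 had higher levels of IL4-response, CD40/NF-κB and MHC class II genes than cells given LPS. They had lower levels of interferon-response, cell-cycle, cholesterol-synthesis and ribosome-biogenesis genes. Of 11957 genes tested, 2560 (21.4%) differed by at least 2-fold at an adjusted p under the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), 1645 of them higher and 915 lower with anti-CD40/IL4. With a filter of 10 CPM in 3 libraries, 1286 of 9051 genes did so. Without a minimum fold change, 10259 genes (85.8%) passed, 5169 higher and 5090 lower, and 4849 passed with an assumed coefficient of variation of 0.2 between cultures. The replicates lay very close together, with a coefficient of variation of 1.57% beyond counting noise, and the first principal component, which parted the stimuli, held 96.5% of the variance. At this spread the test called differences as small as that of Irf4, 1.03-fold, so counts at 2-fold are given beside those at the threshold alone.

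Transcripts that mark the sex of the cells, and transcripts known from T cells, also differed between the groups, and so move with every gene group described here. Xist (gene ID 213742), the RNA that silences one X chromosome in female cells, was at 802 ± 31.1 CPM (SD, n = 3) with anti-CD40/IL4 and at 0.374 ± 0.0749 CPM (n = 3) with LPS. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were present in all 6 libraries. Their summed level was 214 ± 6.55 CPM with anti-CD40/IL4 and 282 ± 0.769 CPM with LPS (n = 3 each), and each of the 4 was lower with anti-CD40/IL4, from a log2 fold change of -0.14 ± 0.03 SE for Eif2s3y to -0.62 ± 0.04 SE for Kdm5d. The sex of the mice is not given in the sources used here. Thy1, a surface glycoprotein of T cells, was at 68.2 ± 1.74 CPM with anti-CD40/IL4 and at 0.409 ± 0.1 CPM with LPS.

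**Figure D1:**
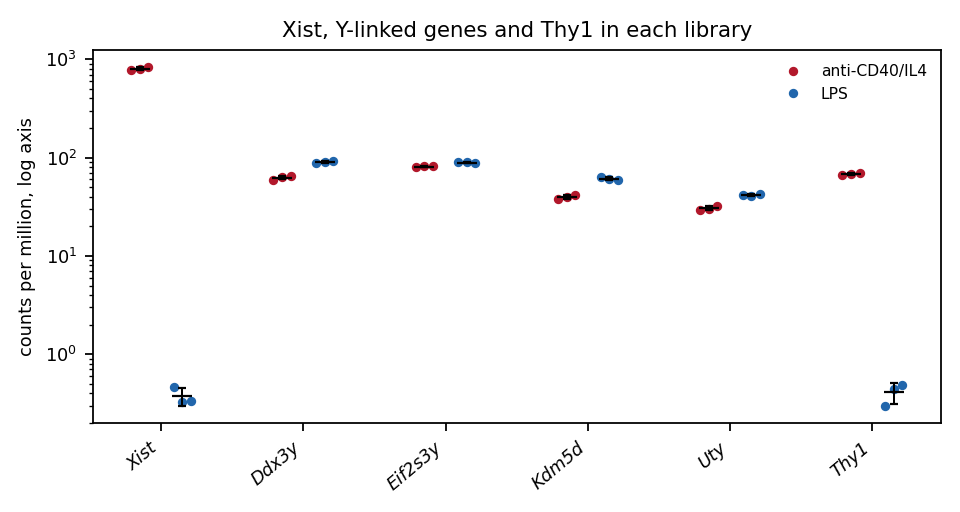
Levels of Xist, 4 Y-linked genes and the surface glycoprotein gene Thy1 in CPM on a log axis; coloured points are the 3 libraries of each group, black marks the mean with its SD. Xist lies near 802 with anti-CD40/IL4 and at 0.374 with LPS, while the Y-linked genes are present in both groups.

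The octamer factor genes differed in opposite directions, and the gene of their coactivator was higher with anti-CD40/IL4. Pou2af1 (gene ID 18985), which encodes OBF1, was 2.15-fold higher with anti-CD40/IL4, at 1464 ± 13.3 CPM against 682 ± 6.93 CPM with LPS (log2 fold change 1.10 ± 0.02 SE, adjusted p = 5.85e-43). Pou2f2 (18987), which encodes Oct2, was 6.89-fold lower, at 56.0 ± 1.93 against 386 ± 2.90 CPM (-2.79 ± 0.02, adjusted p = 3.42e-53). Pou2f1 (18986), which encodes Oct1, was the least abundant of the 3 and was 1.98-fold higher, at 32.3 ± 1.42 against 16.3 ± 1.18 CPM (0.99 ± 0.05, adjusted p = 2.88e-22). These 3 genes are too few for a list test, and their median (0.99) and mean (-0.23) log2 fold changes differ in sign.

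Bcl6 (12053), the repressor required for germinal centre B cells, was 4.00-fold higher with anti-CD40/IL4, at 117 ± 0.408 against 29.2 ± 1.6 CPM (log2 fold change 2.00 ± 0.03 SE). Prdm1 (12142), which encodes Blimp-1, the repressor that drives plasma cell differentiation, was 7.49-fold lower, at 9.78 ± 1.26 against 73.3 ± 2.37 CPM (-2.91 ± 0.05). Aicda (11628), which encodes the deaminase of class switching and somatic hypermutation, differed little, at 89.0 ± 0.508 against 99.3 ± 1.40 CPM (-0.16 ± 0.03). The B cell factors Bach2 (12014) and Pax5 (18507) were lower with anti-CD40/IL4, with log2 fold changes of -0.51 ± 0.02 and -0.32 ± 0.03 SE. Xbp1 (22433), a driver of the secretory state, was higher (0.48 ± 0.02), and Irf4 (16364) was nearly level at 493 ± 9.48 against 477 ± 1.44 CPM (0.05 ± 0.02). The call of Irf4 was lost, at adjusted p = 0.0902 without anti-CD40/IL4 replicate 3, 0.063 without LPS replicate 1, 0.0525 without LPS replicate 2 and 0.0612 without the low-count filter, within a range over the alternatives of 1.64e-07 to 0.893. With an assumed coefficient of variation of 0.2 between cultures, the calls of Aicda (adjusted p = 0.629), Irf4 (0.893), Pax5 (0.291), Xbp1 (0.0942) and Bach2 (0.0722) ended.

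**Figure D2:**
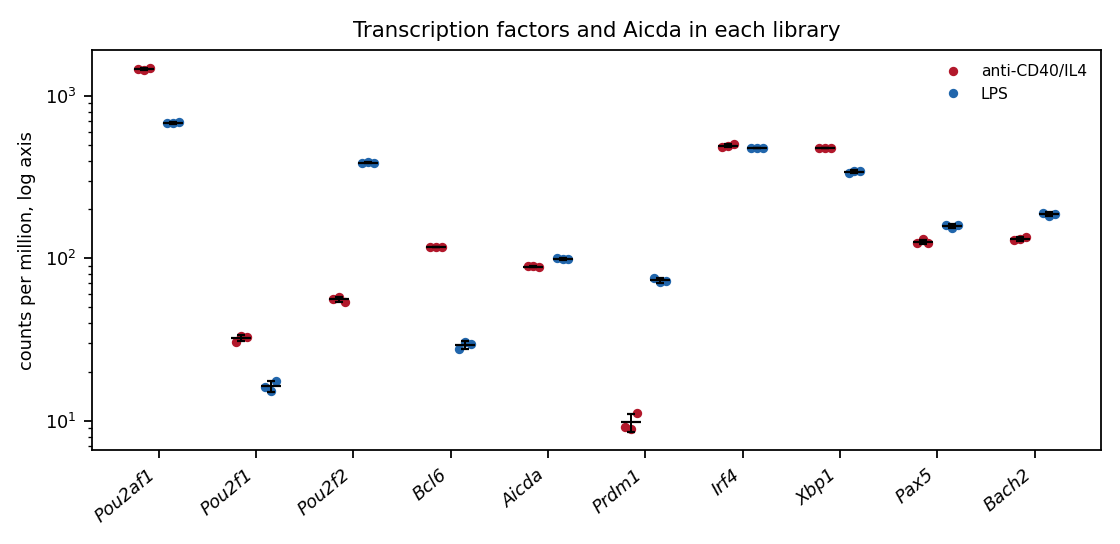
Levels of 9 transcription factor or coactivator genes and Aicda in CPM on a log axis; coloured points are the 3 libraries of each group, black marks the mean with its SD. Pou2af1, Pou2f1 and Bcl6 lie higher with anti-CD40/IL4, Pou2f2 and Prdm1 lie higher with LPS, and Irf4 nearly coincides at 493 and 477.

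The wider germinal centre list leaned towards anti-CD40/IL4 and was mixed. Of 30 tested members, 18 were higher, 10 lower and 2 did not pass; 11 were higher and 4 lower by at least 2-fold. Fas, a death receptor and germinal centre surface marker, was at 171 ± 1.06 against 21.5 ± 0.357 CPM (log2 fold change 2.99 ± 0.03 SE). Il4i1, an IL4-induced amino acid oxidase also counted in the IL4 list, was at 1297 ± 19.8 against 399 ± 3.57 CPM (1.70 ± 0.02). Lmo2, a transcriptional cofactor, was at 117 ± 3.02 against 541 ± 5.47 CPM (-2.20 ± 0.02), and Cxcr5, the receptor that guides B cells into follicles, at 173 ± 1.76 against 385 ± 1.62 CPM (-1.16 ± 0.02). The list passed camera (median 0.52, adjusted p = 0.0035) but not with an estimated correlation (adjusted p = 0.053), with limma-voom (adjusted p = 0.0756) or without the low-count filter (adjusted p = 0.0511). Its adjusted p ranged from 0.00196 to 0.0756 over the camera alternatives.

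The plasma cell list leaned towards LPS, with 16 of 27 tested members lower with anti-CD40/IL4, 10 higher and 1 not past the threshold, and 10 were lower and 4 higher by at least 2-fold. Jchain, which encodes the chain that joins secreted IgM and IgA, was 28.1-fold lower with anti-CD40/IL4, at 5.65 ± 0.310 against 159 ± 2.86 CPM. Ly6a, a surface antigen, was 6.93-fold lower. In the other direction, the surface receptor gene Slamf7 was 9.07-fold higher at 457 ± 5.79 against 50.3 ± 1.25 CPM, and Endou was 3.12-fold higher. The list passed camera (median -0.49, adjusted p = 0.0232) but not with an estimated correlation (adjusted p = 0.10), with limma-voom (adjusted p = 0.116) or without anti-CD40/IL4 replicate 1 (adjusted p = 0.052), over a range of 0.0117 to 0.116. Genes of the endoplasmic reticulum (ER) and secretory pathway differed in both directions, with 26 of 40 lower with anti-CD40/IL4, 11 higher and 3 not past the threshold. By at least 2-fold, 1 was higher (Ddit3) and 1 lower (Derl3, log2 fold change -2.39, named after its value was seen), and the list did not pass (median -0.24, adjusted p = 0.0967). The chaperone gene Hsp90b1 was at 789 ± 8.88 against 1470 ± 26.2 CPM and the disulphide isomerase gene Pdia6 at 261 ± 3.00 against 505 ± 3.42 CPM. Ddit3, the stress-induced factor CHOP, was 6.48-fold higher with anti-CD40/IL4 and Herpud1 1.68-fold higher. The ER list passed without anti-CD40/IL4 replicate 1 (adjusted p = 0.0395), with limma-voom (adjusted p = 0.0305) and without the low-count filter (adjusted p = 0.00986), over a range of 0.00986 to 0.358.

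IL4-response genes were higher with anti-CD40/IL4 in 13 of 14 tested members, 10 of them by at least 2-fold. Their median was 2.21 (camera adjusted p = 9.33e-20, and 0.0135 with an estimated correlation). Fcer2a, the low-affinity IgE receptor CD23, was at 3235 ± 19.4 against 360 ± 2.08 CPM (log2 fold change 3.17 ± 0.02 SE). Cish, a feedback inhibitor of cytokine signalling, was at 172 ± 1.86 against 1.90 ± 0.209 CPM (6.49 ± 0.05). Batf, a factor of the AP-1 family, was the single member that was lower, at 83.9 ± 1.68 against 128 ± 2.13 CPM. The CD40 and NF-κB list was higher in 18 of 27 members and lower in 9, by at least 2-fold in 10 and 1 (median 0.44, adjusted p = 8.75e-07). Nfkb2, the precursor of the non-canonical NF-κB subunit p52, was 3.77-fold higher at 896 ± 3.95 against 238 ± 6.36 CPM, and Fas, also counted in the germinal centre list, was 7.93-fold higher. Bcl3 was 2.82-fold lower and the inhibitor gene Nfkbia 1.46-fold lower, a call that ended with the assumed coefficient of variation (adjusted p = 0.0504). MHC class II and co-stimulation genes were higher in 18 of 21 members and lower in 3, by at least 2-fold in 9 and 1 (median 0.93, adjusted p = 1.90e-10). Of these, Cd40, Cd80, Cd83, Icam1 and Tnfsf4 were also counted in the CD40 and NF-κB list, and Pdcd1lg2 in the IL4 list. H2-DMa and H2-Oa, which edit and restrain peptide loading, were at 1019 ± 15.2 against 152 ± 2.13 CPM and at 196 ± 4.51 against 40.7 ± 0.827 CPM. The co-stimulatory gene Cd86 was 2.95-fold lower and Cd40 itself 1.18-fold lower, a call that ended with the assumed coefficient of variation (adjusted p = 0.447).

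Interferon-response genes were lower with anti-CD40/IL4 in all 39 tested members, 35 of them by at least 2-fold. Their median was -2.52 (camera adjusted p = 2.28e-38, and 0.0135 with an estimated correlation). Oasl1, an antiviral gene, was at 4.78 ± 0.199 against 123 ± 3.16 CPM (log2 fold change -4.68 ± 0.05 SE). Trim30a was at 61.2 ± 1.49 against 339 ± 3.16 CPM (-2.47 ± 0.02), and Bst2, which encodes tetherin, at 24.7 ± 0.691 against 75.4 ± 1.80 CPM (-1.61 ± 0.04). Inflammatory cytokine and TLR-induced genes were lower in 11 of 16 members (8 by at least 2-fold), higher in 4 (2 by at least 2-fold) and not past the threshold in 1, and the list did not pass (median -1.06, adjusted p = 0.217). Il10, an anti-inflammatory cytokine, was 47.4-fold lower with anti-CD40/IL4 at 0.459 ± 0.2 against 21.9 ± 1.37 CPM, and Nfkbiz, an inducible NF-κB cofactor, was 4.60-fold lower. Ltb was 2.50-fold higher and Tnfsf9 3.72-fold higher. TLR4 receptor and signalling genes were lower in 9 of 14 members and higher in 5, by at least 2-fold in 3 each way, with no call for the list (median -0.54, adjusted p = 0.198). The negative regulator Irak3 was 4.31-fold lower and Ly86, which encodes MD-1, 2.30-fold lower, while the adaptor genes Ticam2 and Traf6 were 3.18-fold and 2.03-fold higher. Ly96, which encodes the TLR4 co-receptor MD-2 and was named after its value was seen, was also among the 5 higher, at 18.9 against 8.43 CPM.

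Markers of marginal zone and B1 cells, innate-like B cell subsets, were lower with anti-CD40/IL4 in 9 of 15 members and higher in 6, by at least 2-fold in 7 and 4 (camera, median -0.82, adjusted p = 1.90e-10). The transcriptional repressor gene Zbtb32 was at 1.5 ± 0.343 against 353 ± 3.22 CPM (log2 fold change -7.87 ± 0.05 SE) and the scavenger receptor gene Cd36 at 4.58 ± 0.366 against 307 ± 3.91 CPM (-6.06 ± 0.04). Asb2 and the sphingosine phosphate receptor gene S1pr3 were higher, by 15.8-fold and 2.01-fold. The call was lost with limma-voom (adjusted p = 0.0939, in a range over the alternatives of 1.62e-11 to 0.0939).

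Proliferation genes were lower with anti-CD40/IL4. All 35 mitosis genes were lower, 11 of them by at least 2-fold (median -0.83, adjusted p = 8.45e-16), among them the cyclin gene Ccna2 at 178 ± 2.87 against 460 ± 12.1 CPM and the kinase gene Plk1 at 66.2 ± 1.56 against 182 ± 1.55 CPM. Of 39 DNA replication genes, 36 were lower (9 by at least 2-fold), 1 was higher and 2 did not pass (median -0.74, adjusted p = 3.12e-13). The ribonucleotide reductase genes Rrm2 and Rrm1 were 3.11-fold and 2.61-fold lower. Ribosome biogenesis genes were lower in 27 of 28 members, 2 of them by at least 2-fold (median -0.57, adjusted p = 2.26e-06), with Nolc1 2.18-fold and Mybbp1a 1.84-fold lower. The single exception was Myc, a growth-promoting transcription factor, at 277 ± 5.64 against 157 ± 1.24 CPM.

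Metabolic genes differed by pathway. All 23 cholesterol-synthesis genes were lower with anti-CD40/IL4, 5 of them by at least 2-fold (median -0.82, adjusted p = 9.85e-10), with Fdps 2.36-fold and Cyp51 1.99-fold lower. Oxidative phosphorylation genes were lower in 30 of 32 members, 4 of them by at least 2-fold, and not past the threshold in 2 (median -0.60), with Ndufa4 2.21-fold and Sdhd 1.90-fold lower. Glycolysis genes were higher in 16 of 21 members (5 by at least 2-fold), lower in 4 (0 by at least 2-fold) and not past the threshold in 1 (median 0.59). The last was Gapdh, at 0.539 against 0.646 CPM, whose low counts cannot be read as its expression. The lactate exporter gene Slc16a3 was at 36.2 ± 1.45 against 0.517 ± 0.0686 CPM and the kinase gene Pdk1, which restrains pyruvate oxidation in mitochondria, was 4.59-fold higher. The lactate dehydrogenase gene Ldha and the transporter gene Slc16a1 were 1.36-fold and 1.67-fold lower, and the call of Ldha ended with the assumed coefficient of variation (adjusted p = 0.125). The respiratory and glycolytic lists passed camera (adjusted p = 6.68e-07 and 0.000112) but not with an estimated correlation (adjusted p = 0.151 and 0.144), the highest values over the alternatives, where the lowest were 3.90e-11 and 4.50e-05.

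Several further lists held changes in both directions and did not pass camera. Mature B cell identity genes were lower in 19 of 31 members and higher in 10, by at least 2-fold in 7 and 4 (median -0.27, adjusted p = 0.0651). The adaptor gene Bank1 was 6.99-fold and Fcrl1 4.52-fold lower. Fcer2a, also counted in the IL4 list, was 8.99-fold and the cannabinoid receptor gene Cnr2 3.41-fold higher. The identity list passed without LPS replicate 1 (adjusted p = 0.0365), 2 (0.041) or 3 (0.0465) and without the low-count filter (0.0451), over a range of 0.0365 to 0.169. Class switch and DNA repair genes were lower in 22 of 34 and higher in 8, with 0 differing by at least 2-fold (median -0.23, adjusted p = 0.0967), with Atm 1.89-fold and Exo1 1.93-fold lower and Nbn 1.59-fold higher. This list passed with limma-voom (adjusted p = 0.0332) and without the low-count filter (0.0104), over a range of 0.0104 to 0.189. Targets of p53 were higher in 12 of 19 and lower in 6, by at least 2-fold in 5 and 0 (median 0.44, adjusted p = 0.0534). Fas, also counted in the germinal centre and CD40 lists, was 7.93-fold and Sesn2 1.99-fold higher, and Sesn1 was 1.73-fold lower. The p53 list passed without LPS replicate 2 (adjusted p = 0.0429) or 3 (0.0498) and with upper-quartile factors (0.0473), over a range of 0.0429 to 0.142. Survival and apoptosis genes were higher in 7 of 20 and lower in 13, by at least 2-fold in 2 and 1 (median -0.17, mean 0.04, adjusted p = 0.558). The death receptor gene Tnfrsf10b was 4.52-fold and the survival gene Bcl2l1 1.77-fold higher. Tnfrsf13c, the receptor for the survival factor BAFF, was 2.48-fold and the apoptosis gene Apaf1 1.62-fold lower. Migration and homing receptors were higher in 10 of 20 and lower in 9, by at least 2-fold in 8 and 6 (median 0.15, adjusted p = 0.475), with Cxcr4 5.94-fold and Cd44 2.76-fold higher and Ccr6 4.82-fold and Itgb1 2.59-fold lower.

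**Figure D3:**
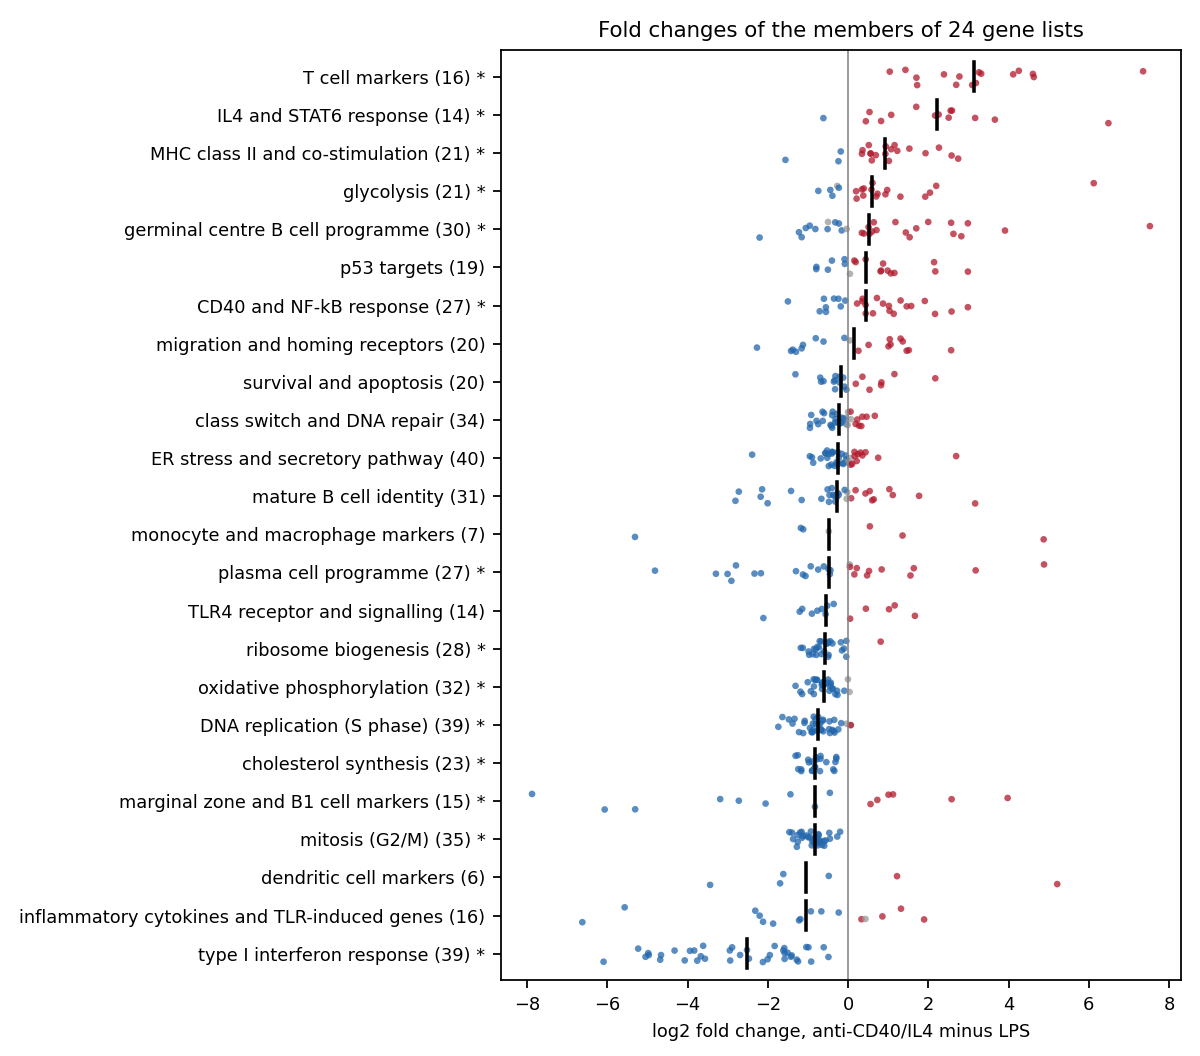
Log2 fold changes, anti-CD40/IL4 minus LPS, of the members of the 24 tested gene lists, with the number of tested members in brackets; red and blue points passed the gene test as higher or lower, grey points did not, black bars are medians, and an asterisk marks lists that passed camera at a preset correlation. The interferon list lies furthest to the left (median -2.52), and the T cell and IL4 lists furthest to the right (medians 3.14 and 2.21).

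Counts adjusted over the list alone were the same as those adjusted over all genes tested in every list except the ER list, where 12 rather than 11 members were higher. With an estimated correlation, 10 of the 14 lists that passed camera still passed, with larger adjusted p-values. The T cell marker list was among them. For the others the adjusted p was 0.0135 (interferon, IL4, DNA replication, marginal zone and B1), 0.0146 (mitosis), 0.0162 (CD40, MHC class II, ribosome biogenesis) and 0.0222 (cholesterol synthesis).

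The tested markers of T cells and NK cells were higher with anti-CD40/IL4, and those of monocytes and dendritic cells differed in both directions. All 16 T cell markers were higher by at least 2-fold (median 3.14, adjusted p = 0.000252, and 0.0353 with an estimated correlation). Besides Thy1, the transcription factor gene Tcf7 was at 33.97 ± 0.245 against 1.77 ± 0.266 CPM and the kinase gene Lck at 84.5 ± 2.15 against 25.6 ± 1.29 CPM. The 6 genes of the T cell receptor complex and CD8 together reached 18.9 ± 1.81 against 1.66 ± 0.170 CPM. Of 10 NK cell markers listed, only 4 passed the expression filter, and all 4 were higher by at least 2-fold. Gzma, a cytotoxic granule protease, had 536 counts against 1 (ratio 596, exact 95% interval 107 to 23597). Prf1 was at 6.03 ± 0.558 against 1.40 ± 0.341 CPM. A marker that passes the filter only through its anti-CD40/IL4 counts, as Gzma did, could hardly come out lower. Of 7 monocyte and macrophage markers tested, 3 were higher and 3 lower, by at least 2-fold in 2 and 3 (median -0.48, while camera's direction was upward, adjusted p = 0.453). Adgre1, which encodes F4/80, was at 54.6 ± 0.613 against 1.85 ± 0.264 CPM, and Itgam, which encodes CD11b, at 0.575 ± 0.151 against 22.9 ± 0.607 CPM. Of 6 dendritic cell markers tested, 2 were higher and 4 lower, by at least 2-fold in 2 and 3 (adjusted p = 0.176), with Zbtb46 37.1-fold higher and Flt3 10.8-fold lower. Few members of the remaining lists were tested: the neutrophil marker Csf3r reached 1.14 ± 0.460 CPM with anti-CD40/IL4, the erythroid marker Hbb-b1 5.27 ± 0.501 CPM with LPS and the mast cell marker Kit 0.536 ± 0.214 CPM with anti-CD40/IL4. The call of Kit ended without anti-CD40/IL4 replicate 1 (adjusted p = 0.232) or 2 (0.0571), without LPS replicate 1 (0.117) or 2 (0.0602), with the DESeq2 Wald test (0.101) and with the assumed coefficient of variation (0.0849), over a range of 0.00494 to 0.232. Among 3 stromal and endothelial markers, the adhesion gene Pecam1 was 3.42-fold lower and Cdh5 2.34-fold higher with anti-CD40/IL4.

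Among genes with a mean of at least 10 CPM and groups that did not overlap, the largest differences towards anti-CD40/IL4 were near-complete contrasts. The sodium channel gene Scn3a (gene ID 20269) had 6088 counts against 2 (ratio 3387, exact 95% interval 937 to 27971). Besides Xist, the others were the chemokine receptor gene Ccr4 (12773) at 51.7 ± 3.36 against 0.0510 ± 0.0157 CPM, the hormone-binding protein gene Crhbp (12919) at 61.6 ± 3.67 against 0.0729 ± 0.0222 CPM and the serotonin receptor gene Htr7 (15566) at 35.4 ± 0.373 against 0.0611 ± 0.0292 CPM. Hspa1a (193740) and Hspa1b (15511), near-identical genes for inducible HSP70 whose reads may be split between them, were at 44.1 ± 0.631 and 55.0 ± 1.66 CPM against 0.0721 ± 0.0168 and 0.114 ± 0.0222 CPM. Parm1 (231440) was at 40.8 ± 1.35 against 0.0929 ± 0.00499 CPM. Towards LPS the largest among such genes were Zbtb32 (58206), Cd36 (12491), Il10 (16153), Itgam (16409), the kinase gene Hck (15162) at 2.85 ± 0.404 against 124 ± 1.90 CPM, Vash1 (238328) at 0.826 ± 0.0154 against 42.1 ± 1.03 CPM, Lrrc25 (211228) at 0.849 ± 0.0786 against 34.01 ± 1.24 CPM, and the gene model 1110032F04Rik (68725) at 0.495 ± 0.164 against 19.8 ± 0.657 CPM.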

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

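The count of genes past the threshold, 10259, stayed within 1.5 times under the settings fixed before the data were examined, but fell to 4849 with an assumed coefficient of variation of 0.2 between cultures, an alternative chosen after seeing the data. The count of genes that differ by at least 2-fold, 2560, was 2557 under that assumption and 2037 with glmTreat, also chosen later. It dropped to 1286 with a filter of 10 CPM in 3 libraries, which tested 9051 genes, and rose to 3230 of 15530 genes without a filter. Leaving out each library in turn gave 10116 to 10174 genes, 2623 to 2650 genes at 2-fold and 14 to 16 lists. The 14 lists called by camera became 10 with an estimated correlation and 24 with fry, which compares no list with other genes. Of the 14, 9 kept the call under each setting they were tested in and 5 lost it under at least 1 (germinal centre, plasma cell, marginal zone and B1, glycolysis and oxidative phosphorylation). The T cell list was not tested with the 10 CPM filter, and no list with glmTreat or the assumed coefficient of variation. No list and none of the 110 named genes reversed in the settings they were tested in. Of these genes, 11 lost the call under at least 1 setting, 8 of them under the assumed coefficient of variation alone; the other 3 were Irf4, Cdt1 and Kit, whose levels differ little or lie near the floor. With the replicate number as a block, 10240 genes, 2557 genes at 2-fold and 15 lists passed; the plasma cell list then missed the threshold (adjusted p = 0.0518) and the ER and class switch lists passed (0.0389 and 0.0495). Libraries with the same number did not deviate together (correlations of their deviations -0.091, 0.023 and 0.024 across 9014 genes above a log2 CPM of 3), so the numbers were not taken as pairs. The alternative without immunoglobulin genes was not run, since 0 rows carried the symbol of an immunoglobulin segment, and pseudocounts did not apply to counts. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 10259 genes, 2560 genes at 2-fold and 14 lists, and was the 1 split with as many in each case. Every other split gave 0 genes at either count but 9 to 12 lists. The number of lists that pass camera at the preset correlation therefore tells little by itself. The other splits also leave the stimuli unequally mixed, so their lists may still reflect the stimulus. Depth does not limit the abundant genes, while genes under about 0.1 CPM in a library cannot be told from 0.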

Other observations

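Beyond the genes named by rule, the next 12 in each direction were read off after their values were seen. Towards anti-CD40/IL4 they included genes usually named for other tissues: Ryr2, the cardiac calcium release channel, at 308 ± 8.07 against 1.03 ± 0.129 CPM (SD, n = 3), Adipoq, the adipocyte hormone adiponectin, at 55.5 ± 1.04 against 0.179 ± 0.106 CPM, and Aire, the regulator of tissue antigens in thymic epithelium, at 23.7 ± 2.11 against 0.185 ± 0.0219 CPM. Tmem176b reached 751 ± 4.57 against 5.53 ± 0.416 CPM. The T cell adaptor gene Lcp2 was at 144 ± 0.399 against 0.597 ± 0.0399 CPM and Cd96, a receptor of T and NK cells, at 65.4 ± 0.499 against 0.275 ± 0.116 CPM. Towards LPS, 6 of the 12 belonged to the interferon-response list (Usp18, Oas2, Rtp4, Mx1, Oasl1 and Isg15), with Isg15 at 4.86 ± 0.388 against 123 ± 3.93 CPM. The others included Fcrl5, counted in the marginal zone and B1 list, at 7.48 ± 0.762 against 296 ± 3.51 CPM, and the carboxypeptidase gene Cpd at 4.27 ± 0.577 against 128 ± 2.10 CPM.

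Of the tests that follow, those on the pooled-sex explanation and on T cells were chosen after the results were seen; those on Y-linked genes for the other explanations and on heat-shock genes were written down before those genes were looked at.

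Xist ran from 769 to 831 CPM in the anti-CD40/IL4 libraries and from 0.327 to 0.460 CPM in the LPS libraries. Groups from mice of different sex were argued against: the summed Y-linked genes were only 1.28 times higher in the lowest LPS library than in the highest anti-CD40/IL4 library, where a male against female contrast needed at least 10. A stimulus that sets the Xist level in cells of one sex stays open. The group means of the Y-linked genes differed 1.32 times, within the bound of 0.5 to 2 set for it. Cells pooled from both sexes can also give a ratio within that bound, so the ratio cannot tell these explanations apart. A pool of male and female cells in the anti-CD40/IL4 cultures also stays open: all 4 Y-linked genes were lower there, but only 2 of 4 X-linked genes that escape inactivation were higher (Kdm6a at 0.51 ± 0.03 SE and Kdm5c at 0.05 ± 0.02 on the log2 scale), with Ddx3x lower (-0.37 ± 0.02), and the stimulus may move these genes too. If the groups differ in the animals pooled, part of any difference in these data could come from that, which the design cannot separate from the stimulus.

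All 16 T cell markers were higher with anti-CD40/IL4, and 3 of them reached 1 CPM with LPS, Lck at 25.6, Itk at 2.90 and Tcf7 at 1.77. Whether carried-over T cells gave the Thy1 level could not be told from a comparison chosen after that level was seen. Such cells with the same transcript ratio in both groups would not give the following values. With anti-CD40/IL4, Thy1 was at 68.2 ± 1.74 CPM, above the sum of the 6 T cell receptor complex and CD8 genes (18.9 ± 1.81). With LPS, Thy1 lay below that sum, at 0.409 ± 0.1 against 1.66 ± 0.170 CPM. The ratio of Thy1 to the sum was 14.7 times higher with anti-CD40/IL4 than with LPS. Carried-over T cells in which the stimuli shifted this ratio stay open, since it was not measured in T cells. For the 6 genes themselves, whose sum was 18.9 against 1.66 CPM, the log2 fold changes spanned 1.91, which is neither the common shift of carried-over cells nor a spread that excludes it, so a small share of T cells or NK cells surviving with anti-CD40/IL4 and a change of these genes in B cells cannot be told apart. The CD19 bead selection would remove most such cells.

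Hspa1a and Hspa1b had 3849 and 4799 counts over the 3 anti-CD40/IL4 libraries and 7 and 11 over the 3 LPS libraries, with an uncertain split of reads between them. A general heat-shock response stays open: the bound set against it beforehand was a median log2 fold change under 0.5 for 10 other heat-shock genes, and the median was -0.070 (-0.0023 with upper-quartile factors), but 4 members were higher and 5 lower, so the median does not decide. The higher ones were Hspb1 (7.11 ± 0.17 SE, 14.8 ± 0.549 against 0.102 ± 0.0315 CPM), Bag3 (0.93 ± 0.12), Dnajb1 (0.63 ± 0.03) and Hsph1 (0.60 ± 0.02). The lower ones included the abundant genes Hspd1 (-0.63 ± 0.02), Hsp90aa1 (-0.52 ± 0.02) and Hspa8 (-0.23 ± 0.02). Whether their high baseline masked a response was not tested. A stimulus-specific switch of these few genes, or a difference between the animals used, was not tested.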
